A study of Arabidopsis thaliana with 12 samples.

How the data were processed

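The series measured total RNA of Arabidopsis thaliana, ecotype Columbia 0, on 12 arrays, with 6 from wild type (WT) and 6 from the cue1-1 mutant, here called cue1. Groups and sample numbers were taken from the sample titles. The deposited values are spot intensity values on a linear scale, with 1 value per probe and array for 3439 probes. In the deposited values every array reaches its maximum at 100 and holds exact zeros, and the column medians differ between arrays by up to 1.60 on the log2 scale. The array type, the scanner, how the background was removed and how the values were brought to this range are not given in the sources used here. The tissue and the growth conditions are not stated either. The number of arrays limits the precision of each comparison.

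Because the column medians lay more than 0.1 apart on the log2 scale, the 12 columns were quantile-normalized. Values below the 5th percentile of all positive normalized values were then set to that percentile (0.0179, or -5.80 on the log2 scale), and log2 was taken. No probe was left out. Values at this floor in the lower group make a log2 difference too small and those in the higher group make it too large, so differences that rest on the floor have no exact size or order. Each probe was tested for cue1 minus WT, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over the 3439 probes, with a threshold of 0.05. Changed, higher, lower, rose and fell refer to this threshold. The fit had no covariate. Sample numbers are shared by the groups, but nothing in the labels says that they pair samples, so the fit with the number as a block was an alternative.

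Genes were named from the array platform's annotation, which can be old, and updated through the reference gene table of assembly TAIR10.1, used for names only. Of the probes, 692 carried 1 gene name (691 genes), 870 carried several and 1877 were unnamed here. Of the 692, 690 matched the reference table and 2 did not. No gene was named from a probe with several names. By the rule set before the data were examined, the text names PPT1 and PPT2, the 12 genes with the largest rise and the 12 with the largest fall among single-gene probes past the threshold whose 6 cue1 values do not overlap the 6 WT values, and, for each gene list, up to 3 called members with the largest change or, where none is called, the member with the smallest p. PSB27, PSBY, PPDK, AT1G24360 and AT1G74470, the remaining measured members of the short lists, and the genes called under all 4 scalings were named after their values were seen.

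A set of 24 gene lists with 429 members was fixed before the data were examined. They cover PPT1 and its homologue, photosynthesis, plastid metabolism, transport, protein import and ribosomes, nitrogen and phenylpropanoid metabolism, photorespiration, stress, tissue markers and reference genes. Another 10 lists were written after the probe names and the intensities of the brightest spots had been seen, but before any difference was computed. Lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted by Benjamini-Hochberg separately over the fixed and over the added lists.

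The alternatives set before the data were examined were no normalization, median centring, cyclic loess, the dimmest 25% of probes left out, a pseudocount in place of the floor, a floor at the 1st percentile, the replicate block, array weights, trended and robust eBayes, unmoderated statistics and each array left out in turn. Alternatives that leave out or combine arrays numbered 5 and 6 or consecutively numbered arrays, or that leave out probes beside bright spots, were chosen after seeing the data. The limma step was tested on simulated data for cue1 against WT, with 3439 probes drawn from the real means and spreads. It recovered 16.4% of 67 probes changed by 0.5, 32.8% of 67 changed by 1 and 71.2% of 66 changed by 2 on the log2 scale, and 4.76% of its calls were unchanged probes. The simulated arrays were independent, and apart from the changed probes the groups differed by a uniform factor. These shares therefore do not cover correlated arrays or a group shift that depends on intensity.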

Results

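Transcript levels in the cue1-1 mutant were compared with those in WT on 12 arrays, 6 per genotype. The mutant lacks, according to the sample labels, a translocator that carries phosphoenolpyruvate, which in plants brings this precursor of the shikimate pathway into plastids. The median deposited intensity was 0.388 to 0.411 on WT arrays 1 to 4, 0.246 and 0.239 on WT arrays 5 and 6, and 0.136 to 0.158 on the cue1 arrays. Between 153 and 186 of the 3439 probes were listed at 0 on a WT array and between 259 and 501 on a cue1 array. From 2 to 5 spots per array lay at the maximum of 100. The labels do not say that the samples come from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.

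**Figure D1:**
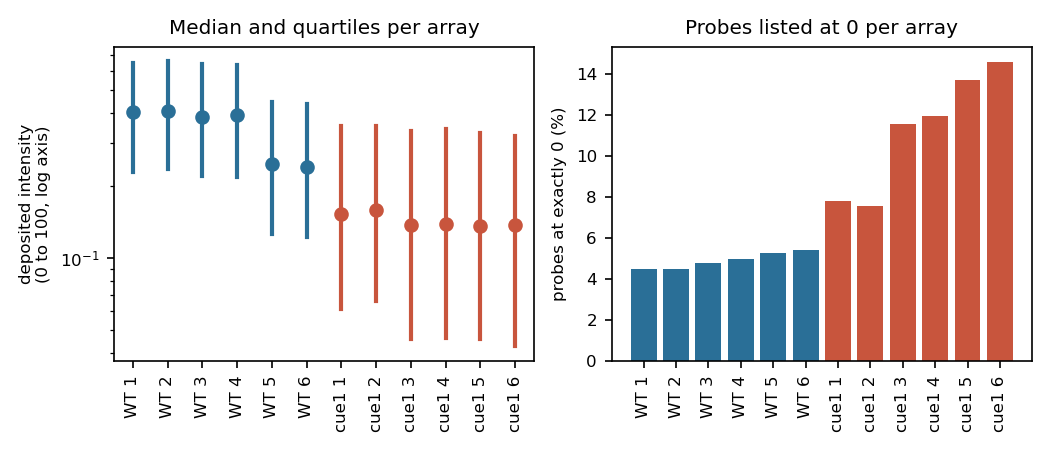
Deposited intensity per array before any scaling. Left, the median (point) and the quartiles (line) of the 3439 probes on a log axis; right, the percentage of probes at exactly 0. The 6 cue1 arrays have lower medians than the 6 WT arrays and a higher share of zeros, from 7.53% to 14.6% against 4.45% to 5.41%.

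The comparison of cue1 with WT asked which transcripts change when the translocator is missing. The gene of the translocator, PPT1, had no probe carrying its name alone, nor had its homologue PPT2, so the labels were not checked against the targeted gene. After quantile normalization, 376 probes were higher and 356 lower in cue1, together 732 of 3439 or 21.3% (limma, Benjamini-Hochberg adjusted p below 0.05). The median absolute log2 difference of these probes was 1.03. Before adjustment, 1292 of the 3439 probes had a limma p under 0.05. The 6 cue1 values did not overlap the 6 WT values for 378 of the 3439 probes, of which 364 were past the threshold. Chance gives 0.216% of probes if all arrays are independent samples. That share does not hold if consecutively numbered arrays are repeat measurements, which the labels do not settle. Among the 692 single-gene probes, 70 were higher and 68 lower, together 138.

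Transcripts that rose most among the named genes included AILP1 (AT5G19140), which encodes a protein similar to aluminium-induced proteins, DI21 (AT4G15910), a drought-induced gene, and AT4G26900 (AT-HF), which encodes an enzyme of histidine synthesis. The log2 difference was 2.59 (SE 0.24, limma adjusted p = 9.04e-05) for AILP1 (1.69 with cyclic loess), whose WT values were at the floor on 3 of 6 arrays. It was 1.74 (SE 0.21, limma adjusted p = 0.000460) for DI21 and 1.72 (SE 0.26, limma adjusted p = 0.00133) for AT4G26900. AT5G14910 rose by 1.83 (SE 0.20, limma adjusted p = 0.000224) and AT1G78620 by 1.54 (SE 0.29, limma adjusted p = 0.00463). As the rule for this set of 12 requires, all 6 cue1 arrays lay above all 6 WT arrays in each of its genes. The other genes in this set of 12 were AT2G37880 (2.31, with 2 of 6 WT arrays at the floor), AT4G13550 (2.23), AT3G20150 (1.84, with 1 of 6 WT arrays at the floor), AT1G65090 (1.81), AT5G67490 (1.66), AT2G29180 (1.49) and AT3G56250 (1.33, but -0.18 without normalization). The call of AT3G20150 ended without WT 1, 2 or 3 or cue1 1, 3, 5 or 6 (1.56 to 1.87), and that of AT3G56250 without WT 1 or 2 or any 1 of the cue1 arrays (1.08 to 1.39).

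Transcripts that fell included AT1G11820, which encodes a glycosyl hydrolase, AT2G19870, which encodes an RNA methyltransferase, and AT1G76050, which encodes a pseudouridine synthase. AT1G11820 was listed at 0 on all 6 cue1 arrays and had a mean deposited intensity of 0.369 (SD 0.116, n = 6) in WT. AT1G76050 fell by 1.98 (SE 0.39, limma adjusted p = 0.00533), with 2 of 6 cue1 arrays at the floor, and AT2G19870 fell by 1.73 (SE 0.35, limma adjusted p = 0.00613). AT3G32940 fell by 1.51 (SE 0.21, limma adjusted p = 0.000745). AT2G23890 (-3.11) was at the floor on 5 of 6 cue1 arrays, and its probe lies within 3 probe numbers of a spot with a mean intensity of 20.6. AT1G32220 (-2.36), at the floor on 2 of 6 cue1 arrays, lies as close to a spot with a mean of 74.0. The other genes of this set of 12 were AT1G50750 (-2.94), AT1G50020 (-2.25), AT2G38070 (-2.25), AT1G05340 (-2.11), AT5G01860 (-1.85) and AT3G02450 (-1.70), which were at the floor on 4, 2, 3, 1, 1 and 1 of 6 cue1 arrays, so their order was not measured. With cyclic loess the first 3 of these differed by -1.27, -1.27 and -1.44, AT2G23890 by -1.47 and AT1G32220 by -1.25, all called. The call of AT1G50020 ended without WT 1, 2 or 3 (-2.34 to -2.20), that of AT5G01860 without WT 2, 3 or 4 (-1.89 to -1.82), and that of AT3G02450 without any 1 of the WT arrays or cue1 1, 2, 3 or 4 (-1.83 to -1.65). Without cue1 5, where both were at the floor, AT3G02450 was at -1.10 and AT5G01860 at -1.29, and both were called.

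**Figure D2:**
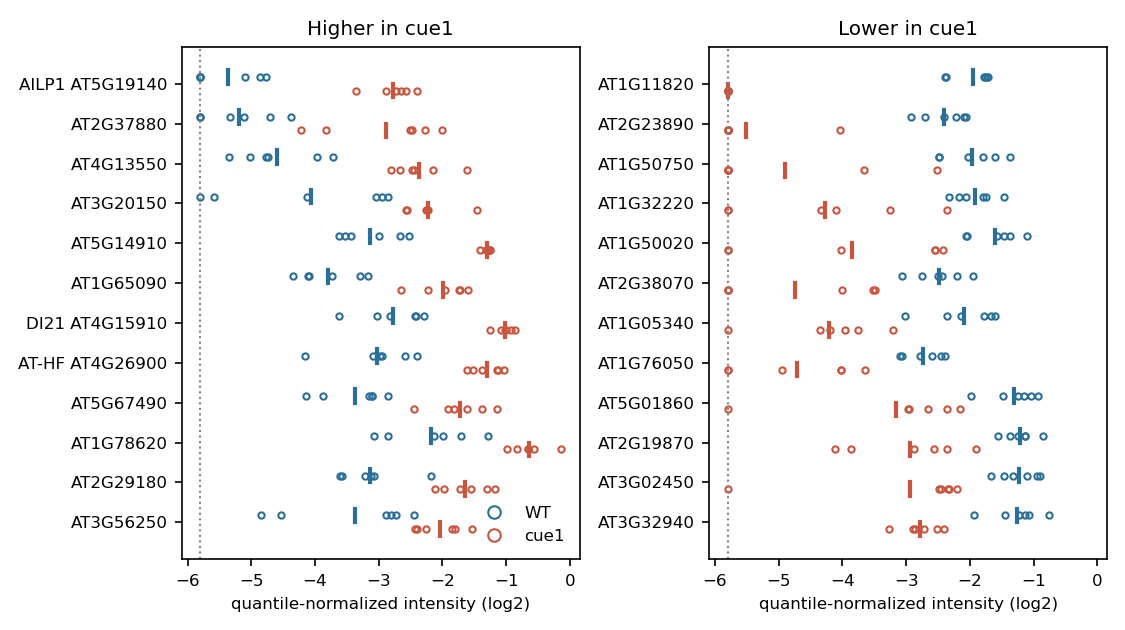
Quantile-normalized log2 intensity of the 12 named genes that were higher (left) and the 12 that were lower (right) in cue1. Each circle is an array (6 WT, 6 cue1), each bar a group mean, and the dotted line the floor at -5.80, where values have no order. The genes were chosen so that the groups do not overlap.

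The balance of higher and lower calls depended on the scaling between arrays. It was 51.4% higher with quantile normalization, 5.37% (110 higher, 1938 lower) without normalization and 71.9% (1175 higher, 460 lower) with median centring. The median log2 difference of all probes was -0.95 without normalization and 0.29 with median centring. On the deposited values themselves 4 of the 12 higher genes were called, which were AT5G14910, DI21, AT4G26900 and AT1G78620, and all 12 of the lower. Relative to the median of -0.95 in that setting, all 12 higher genes lay above and all 12 lower genes below. These genes were chosen for large differences in the same data, so this is no separate support for them. Over all probes, 78 were higher and 177 lower under each of quantile normalization, no normalization, median centring and cyclic loess. Median centring shifts every difference found without normalization by the same constant, so the 4 scalings are not 4 separate checks. The shift without normalization favours lower calls in these counts. When arrays with consecutive numbers were averaged in pairs or fitted as a random block, the 732 calls became 103 or 397.

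**Figure D3:**
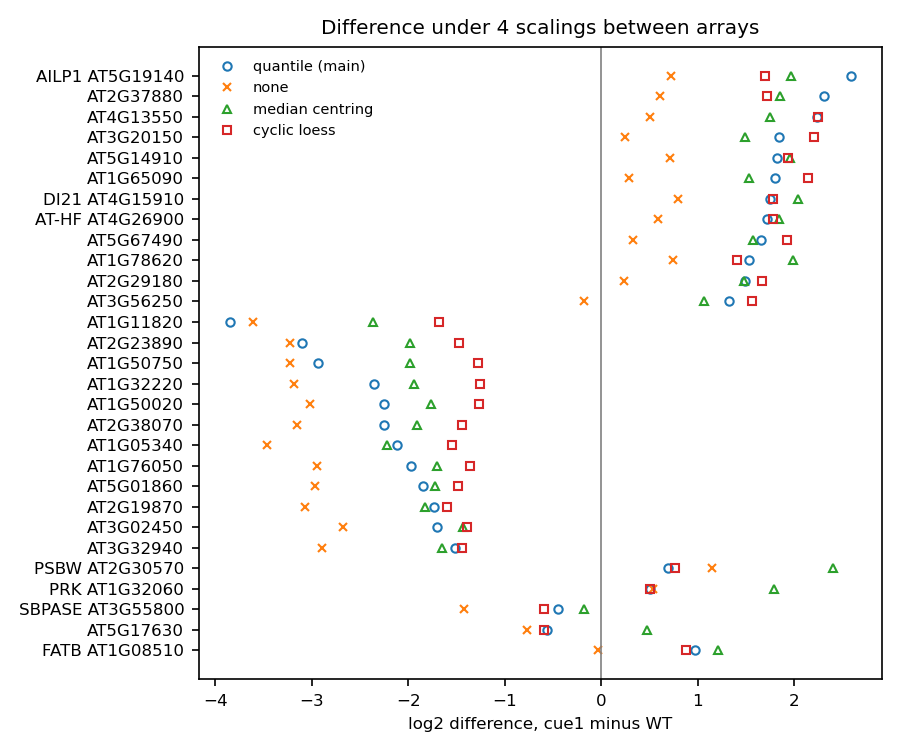
Log2 difference, cue1 minus WT, of the 24 named genes and of the 5 called members of the fixed lists under 4 scalings between arrays, 1 marker per scaling. AT3G56250 (-0.18) and FATB (-0.04) turn negative without normalization and AT5G17630 turns positive (0.48) with median centring; the other genes keep their sign.

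Photosynthesis genes with a named probe were few. Of the 3 measured subunits of photosystem II, PSBW rose and the other two did not pass the test. PSBW was higher by 0.69 (SE 0.19, limma adjusted p = 0.0233) on all 6 cue1 arrays, with a mean deposited intensity of 63.9 (SD 10.8, n = 6) in cue1 and 28.8 (SD 4.95, n = 6) in WT. It was called higher under all 4 scalings, at 2.40 with median centring. PSB27 had a difference of 1.39 (SE 0.57, limma adjusted p = 0.101) and PSBY one of -0.31 (SE 0.17). The light-harvesting gene LHB1B2 (AT2G34420) differed by 0.01 (SE 0.10, limma adjusted p = 0.943), and by 0.41 without normalization and 1.66 with median centring, both of which were called. Photosystem I subunit PSAN differed by -0.29 (SE 0.20, limma adjusted p = 0.307), and by 1.11 with median centring, which was called.

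Both measured Calvin-Benson cycle genes changed. PRK, which encodes phosphoribulokinase, was higher by 0.51 (SE 0.15, limma adjusted p = 0.0356), and SBPASE, which encodes sedoheptulose-bisphosphatase, fell by 0.45 (SE 0.13, limma adjusted p = 0.0342). PRK was called under all 4 scalings (1.79 with median centring), and its call ended without WT 1, 2, 3 or 4 or cue1 3, 5 or 6 (0.41 to 0.51). SBPASE was at -1.42, called, without normalization. Its call ended with median centring (-0.17) and without WT 3, 4 or 6 or cue1 1, 2 or 4 (-0.46 to -0.38).

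Among plastid envelope transporters and enzymes of phosphoenolpyruvate metabolism, 2 genes were measured. AT5G17630, which encodes the plastid translocator for pentose phosphate, fell by 0.56 (SE 0.12, limma adjusted p = 0.00710) with all 6 cue1 arrays below all WT arrays, but lay at 0.48, called, with median centring. PPDK, which makes phosphoenolpyruvate from pyruvate, differed by 0.10 (SE 0.12). In plastid fatty acid synthesis, the acyl-ACP thioesterase gene FATB rose by 0.97 (SE 0.24, limma adjusted p = 0.0142) but differed by -0.04 without normalization, and its probe lies within 3 probe numbers of a spot with a mean intensity of 10.6; the ketoacyl-ACP reductase gene AT1G24360, with 1 of 6 cue1 arrays at the floor, differed by 0.14 (SE 0.49). The chlorophyll synthesis genes CHLM and AT1G74470 differed by -0.35 (SE 0.28) and 0.15 (SE 0.14) and the peroxiredoxin gene AT3G52960 by 0.28 (SE 0.24; 0.17 without WT 5), and none of these passed the test. CHLM was called without normalization (-1.42) and AT3G52960 with median centring (0.83).

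The plastid ribosomal protein list was not called by camera under any of the 4 scalings. None of the 6 measured members passed the limma test, and 0 had an unadjusted p under 0.05; 4 had a positive sign, the median difference was 0.06 and the mean 0.21 (camera p = 0.533, or p = 0.595 with an estimated correlation, and fry p = 0.319). AT4G01310, the gene of ribosomal protein L5, differed by 0.36 (SE 0.24, limma adjusted p = 0.289), by 0.23 without WT 1, by -0.37 without normalization and by 0.87 with median centring, which was called. The list mean was 0.65 with median centring. Over all fixed lists, 20 of 429 members were measured by a single-gene probe, of which 3 rose and 2 fell; adjusted over the list alone, PSB27 was the sole member to join them. The other 15 lists, among them the shikimate pathway and phenylpropanoid synthesis, had no measured gene.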

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

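The tests on consecutively numbered arrays, on the dim spots and on the share of zeros beside bright spots were chosen only after the result was seen, and the shares of calls by brightness had been seen before the test on bright spots. In 6 of the 91 groups of 6 values tested for the named genes, 1 array stood apart from the other 5 by Dixon's test at the 95% level, where chance gives about 1 in 20, or 4.55. That rate does not hold where values were set to the floor, as for AT2G23890, AT5G01860, AT3G02450 and GLX2-1 below. In cue1, AT3G20150 was at -1.46 on array 6 and between -2.57 and -2.23 on the others (ratio 0.697). AT2G23890 was at -4.04 on cue1 array 2 and at the floor of -5.80 on the others, which fixes the ratio at 1. AT5G01860 was at the floor on cue1 array 5 and between -2.98 and -2.15 on the others (ratio 0.773). AT3G02450 was also at the floor on cue1 array 5 and between -2.48 and -2.20 on the others (ratio 0.920). GLX2-1 (AT2G43430) was at the floor on cue1 array 2 and between -3.89 and -2.90 on the others (ratio 0.658). In WT, AGL26 (AT5G26880) was at -4.19 on array 1 and between -2.38 and -1.78 on the others (ratio 0.752).

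Many probes differed between cue1 and WT, 732 in all. Of 100 splits of the 12 arrays into 6 and 6, only 1, the real one, gave as many, and the highest of the other splits gave 6. This makes chance an unlikely source only if the arrays are independent samples, which the correlations of consecutive arrays given below put in doubt. The 10 splits that keep arrays 1 and 2, 3 and 4, and 5 and 6 of a group together are too few for a share under 0.05 (real split 732, highest other 2). A background difference that moves dim spots does not account for the whole count, because 29.0% of the 100 spots with a mean intensity above 4 were called (exact 95% interval 20.4% to 38.9%). Repeat measurements counted as independent samples may inflate the count: pairs 1 and 2, 3 and 4, and 5 and 6 had a consensus correlation of 0.323, the highest of 15 ways of pairing (next 0.0473), and as a random block they left 397 calls, although the log2 values of cue1 5 and 6 correlated at 0.791, within the range of other cue1 pairs (0.788 to 0.851), and their deviations from the group mean at -0.160, above the highest other pair (-0.202). A difference between the genotypes stays open beside this, as does any difference in growth or handling that coincides with genotype.

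Deposited values of dim spots were lower in cue1, with a median log2 difference of -1.34 in the dimmer 50% of probes against -0.25 in the brightest 25%. WT arrays 5 and 6 differed from WT arrays 1 to 4 in the same way, by -0.75 (bootstrap interval over probes, not over arrays, -0.80 to -0.71) and -0.19. An array-level difference in background or exposure not tied to genotype is therefore a candidate explanation. A lower level of most transcripts in the mutant relative to the brightest ones cannot be told apart from this, because no probe of a known amount was identified and the brightest spots of every array are at 100.

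Probes beside a bright spot were listed at 0 on cue1 arrays more often than others, and this touches AT2G23890 and AT1G32220. Of 132 probes 1 or 2 numbers from a spot with a mean intensity above 10, 50.8% (exact 95% interval 41.9% to 59.6%) had a zero on a cue1 array, against 23.4% (19.1% to 28.1%) at 5 to 10 numbers and 29.2% beside spots of 1 to 10; on WT arrays the share was also higher, 16.7% (10.7% to 24.1%) against 8.54% (5.88% to 11.9%) and 8.51%, with intervals that overlap. Beside refers to probe numbers, and the sources used here do not give spot positions. A background value taken from the neighbourhood of bright spots would give such a pattern only if probe numbers follow position. No rise was seen between neighbours under 1 (29.1%) and of 1 to 10. Co-regulation of neighbouring probes, the biological alternative, found no support. Of the 34 probes beside the 12 called bright spots, 17 (50%) had the sign of that spot's difference, the share that chance gives. The exact 95% interval of 32.4% to 67.6% is too wide to exclude it. Without the probes within 3 numbers of such spots, 672 of 3244 probes were called.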

How the results depend on the processing

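The settings on arrays 5 and 6, on consecutive numbers and on probes beside bright spots were chosen only after the result was seen. The count of 732 (376 higher, 356 lower) stayed within 1.5 times under cyclic loess (726), the dimmest probes left out (690), a pseudocount (744), the lower floor (668), array weights (807), trended and robust eBayes (832), unmoderated statistics (653), WT 5 and 6 left out (771), 5 and 6 of both groups left out (730), probes beside bright spots left out (672) and consecutive numbers as a fixed block (931). It was 544 to 729 with 1 array left out (285 to 396 higher, 259 to 343 lower). It was 2048 (110 higher, 1938 lower) without normalization and 1635 (1175 higher) with median centring, where the median of all probes moved. It was 103 (49 higher, 54 lower; 94 shared) with consecutive samples averaged, which leaves fewer samples, and 397 (211 higher, 186 lower) with them as a random block. The replicate block gave 702 calls, 594 of them shared with the fit without it, and ended the call of the amino acid list (camera adjusted p = 0.0819). Deviations of same-numbered samples correlated at 0.172, 0.199, 0.120, 0.104, 0.0582 and 0.0774, all positive. Among samples of the other genotype, every sample correlated best with its own number. A pairing by number therefore cannot be set aside, although the labels do not state one. Of the 24 genes of the higher and lower sets, 24 kept their call under cyclic loess and median centring, 16 without normalization, 22 under the replicate block, 18 with the random block and 13 with consecutive samples averaged. Leaving out the dimmest probes removed 10 of the 24 and left the plastid ribosomal list under 5 genes. PPT1 gave no value under any setting, and camera does not use the eBayes settings or the random block. How far the signal lies above background is not known, and this limits the dim probes.

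Without normalization the mean of these lists turned negative: plastid ribosomal proteins (-0.60; 0.11 to 0.30 with 1 array left out), thylakoid assembly (-0.98), amino acid enzymes (-0.34), mTERF (-1.04), mitochondrial respiration (-0.69) and reproductive regulators (-1.13). So did AT3G56250 (-0.18), AT4G01310 (-0.37), FATB (-0.038), AT3G52960 (-0.42), APS4 (-0.43), AT3G58610 (-0.35), AT1G79220 (-0.16) and AT5G47030 (-0.27). With median centring PSAN (1.11), AT5G17630 (0.48), AT3G26630 (0.78) and the pigment (0.091) and pentatricopeptide (0.068) lists turned positive. The shift of the median of all probes goes with these signs. Values near 0 also crossed it: the thylakoid list with the dimmest probes left out (-0.012), with the lower floor (-0.015) and with 1 array left out (-0.059 to 0.044), the redox list with the dimmest probes left out (0.099), LHB1B2 with array weights (-0.010), 1 array left out (-0.018 to 0.043), WT 5 and 6 left out (-0.025) and 5 and 6 of both groups left out (-0.055), and AT3G52960 under this last setting (-0.046). The cause was not tested.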

Other observations

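The gene lists in this part were written after the probe names had been seen, and the genes called under all 4 scalings were chosen after their values were seen. Enzymes of amino acid, nucleotide and sulfate metabolism tended to be higher in cue1. Of 9 measured members, 3 rose and none fell, 7 had a positive sign and the median log2 difference was 0.73 (camera adjusted p = 0.0424, adjusted p = 0.208 with an estimated correlation, fry adjusted p = 0.00108); the mean was -0.34 without normalization. The 3 were AT4G26900 of histidine synthesis (1.72), the sulfate-activating ATP sulfurylase gene APS4 (0.90, SE 0.22, limma adjusted p = 0.0142) and AT3G58610 of branched-chain amino acid synthesis (0.73, SE 0.17, limma adjusted p = 0.0131), of which APS4 (-0.43) and AT3G58610 (-0.35) turned negative without normalization. The probe of AT3G58610 lies within 3 numbers of a spot with a mean intensity of 10.3. Adjusted over the list alone, 5 rose. The call of the list ended without WT 1, 2 or 6 or cue1 3, 4 or 6 (mean 0.73 to 0.79). It held in 14 of 28 settings, fry among them (fry adjusted p = 0.00108), which does not compare the list with other genes. The camera adjusted p ran from 0.0188 to 0.208. The call also ended in camera without normalization (adjusted p = 0.189), with median centring (adjusted p = 0.136) and with array weights (adjusted p = 0.0698). The same held in camera for the replicate block (adjusted p = 0.082) and for arrays 5 and 6 of both groups left out (adjusted p = 0.123). Camera also lost it with consecutive numbers as a fixed block (adjusted p = 0.0906) and with probes beside bright spots left out (adjusted p = 0.122). The mean was -0.34, 0.90, 0.75, 0.79, 0.82, 0.79 and 0.79 in this order, against 0.79.

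Single genes for organelle gene expression and respiration passed the test, and camera called none of their lists. Such calls were common, since 138 of the 692 single-gene probes passed, so the counts here are no sign of a change particular to these genes. Of 19 pentatricopeptide repeat genes, which act on organelle RNA, 2 fell: AT5G15280 by 1.05 (SE 0.17, limma adjusted p = 0.00204), called under all 4 scalings, and AT3G26630 by 0.38 (SE 0.12, limma adjusted p = 0.0410), which was 0.78 with median centring and not called with cyclic loess (-0.37). Their list had a median of -0.19 (camera adjusted p = 0.705, fry adjusted p = 0.0445). Of 6 mitochondrial respiration genes, AT4G02580 of complex I (1.72, a value that rests on the floor, where 4 of 6 WT arrays and 1 of 6 cue1 arrays lay, but 0.30 without normalization and 0.81 with cyclic loess, neither called) and AT5G47030 of the ATP synthase (1.11, SE 0.29, but -0.27 without normalization) rose (list camera adjusted p = 0.736). Of 6 mTERF genes AT1G79220 rose (0.56, SE 0.18, but -0.16 without normalization and 0.43, not called, with cyclic loess; list camera adjusted p = 0.838). Of 6 regulators of reproductive development AGL26 rose (1.13, SE 0.37, but 0.10, not called, without normalization; list camera adjusted p = 0.842). The calls ended with single arrays left out for AT3G26630 (WT 1, 3, 4, 6, cue1 1, 2, 5, 6; -0.38 to -0.34), AT4G02580 (WT 1, 2, 3, cue1 1, 2, 3; 1.47 to 1.76), AT1G79220 (WT 1, 2, 4, 6 or any cue1 array; 0.49 to 0.61) and AGL26 (WT 2, 5 or any cue1 array; 1.05 to 1.19; 0.79, called, without WT 1). The probes of AT3G26630, AT4G02580 and AT5G47030 lie within 3 numbers of spots with a mean intensity above 10.

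Camera with quantile normalization called none of the other plastid lists. SECE1, a subunit of the thylakoid Sec translocase, fell by 0.61 (SE 0.15, limma adjusted p = 0.0142), as the sole call among 14 thylakoid assembly and NDH complex genes (camera adjusted p = 0.940, fry for change in either direction adjusted p = 0.00342); its call ended with median centring (-0.20) and held without normalization (-1.45). With photosynthesis lists pooled, 2 of 7 genes rose and 1 fell (camera adjusted p = 0.842, fry for either direction adjusted p = 0.000181). Fry does not compare a list with other genes, and 732 of all 3439 probes were called. It also takes the 12 arrays as independent samples. The low fry values are therefore not particular to these lists. Camera called the pooled list higher without normalization (mean 0.23, adjusted p = 0.000104) and with median centring (mean 1.47, adjusted p = 0.0436), where the median of all probes was -0.95 and 0.29. None of 5 pigment synthesis genes (median -0.38, camera adjusted p = 0.705, fry adjusted p = 0.0519), 6 plastoglobule genes (median -0.09, camera adjusted p = 0.842) and 6 plastid redox genes (median 0.03, camera adjusted p = 0.940) passed the limma test, and 2, 2 and 1 of them had an unadjusted p under 0.05. These counts are to be read against all probes, of which 1292 of 3439 had an unadjusted limma p under 0.05. The redox list had a mean of -0.10, and camera's direction was down for it and for the thylakoid list, whose median (0.03) and mean (0.0094) were positive. SIRB differed by -0.41 (SE 0.16), GLX2-1 by -1.07 (SE 0.42, but -0.67 without cue1 2, where it was at the floor) and the fibrillin gene AT5G19940 by -2.01 (SE 0.81, with 3 of 6 cue1 arrays at the floor), the last within 3 numbers of a spot with a mean intensity above 10 and called without cue1 array 2 (-2.45). GLX2-1 was called lower under the other 3 scalings (-2.67 without normalization, -1.42 with median centring, -0.96 with cyclic loess), AT5G19940 under no normalization (-2.63) and median centring (-1.38), and SIRB without normalization (-1.47).

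Of the single-gene probes, 12 were higher and 39 lower under all 4 scalings. The median of -0.95 without normalization favours lower calls in these counts. No normalization and median centring give the same differences apart from a constant, so the scalings are not all separate checks. The 12 include CCL (AT3G26740), a light-regulated gene, with a difference of 0.97 (SE 0.13, limma adjusted p = 0.000602), and FZL (AT1G03160), which encodes a chloroplast protein of thylakoid organization, with 0.82 (SE 0.15, limma adjusted p = 0.00329). The mean deposited intensity of CCL was 6.18 (SD 0.997, n = 6) in cue1 and 2.90 (SD 0.256, n = 6) in WT. MAMI (AT5G54110) rose by 1.18 (SE 0.14, limma adjusted p = 0.000460), AT4G39760 by 0.89 (SE 0.14, limma adjusted p = 0.00187) and AT1G49850 by 1.18 (SE 0.19, limma adjusted p = 0.00162), each with all 6 cue1 arrays above all WT arrays. CSLA01 (AT4G16590), which encodes a mannan synthase, rose by 1.13 (SE 0.25, limma adjusted p = 0.00908). Among the 39, RAP74 (AT4G12610), a subunit of a general transcription factor, fell by 0.83 (SE 0.18, limma adjusted p = 0.00791).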
